A study of Ictalurus furcatus with 60 samples.

How the data were processed

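RNA was measured by sequencing in sperm of 30 male blue catfish (Ictalurus furcatus). Per the labels' protocols, the sperm of each male was split into a part put directly into a deep freezer, labelled fresh, and a part taken through a cryopreservation procedure, and RNA of both parts was extracted with a column kit and made into libraries with a kit for total RNA depleted of ribosomal RNA. The labels also name the molecule as polyA RNA, which does not go with that kit, so the RNA fraction is uncertain. One library per male and treatment gave 60 libraries in 2 groups of 30, and the male number in the title names each sample and pairs its fresh and cryopreserved library. One fresh library, of male 43, carries another trailing number in its column name than in its label, and it was assigned by male and treatment, which match no other sample.

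The authors deposited raw read counts per gene, as whole numbers, in one table for each treatment. Per the submitters' processing notes, the tools used upstream were FastQC 0.11.6, Trimmomatic 0.39, TopHat2 2.1.1 and bedtools, with no role or order given. The genome build, the annotation and the counting rule are not given in the sources used here. Both tables list the same 33677 gene identifiers, once a leading space was removed. All 60 count columns were assigned to a sample, and 0 columns were left unused. Over all deposited count columns, 68299 entries were exactly 2 and 22461 were exactly 1, and 58 of the 60 libraries held more genes at 2 counts than at 1. Whether the read mates of a fragment were counted separately is not given in the sources used here, so a count of 2 need not be 2 molecules. The closest pair of libraries, the cryopreserved library of male 4 and the fresh library of male 1, differed by a chi-square of 2.91 per degree of freedom. This sets them against the error of independently counted reads only, which is too small an error if mates were counted separately, so the value alone does not exclude a repeated library. The pair differs in male and treatment per the labels, and every library was kept as a sample of its own. In the cryopreserved library of male 4 the 10 most abundant genes took 0.792% of the counts. They took 0.796%, 0.786% and 0.779% in the fresh libraries of males 1, 2 and 3. In the fresh library of male 4 they took 2.43%, and 3.36%, 3.35% and 3.22% in the cryopreserved libraries of males 1, 2 and 3. Whether the treatment labels of male 4 are right was not tested.

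The deposited tables hold no gene names, and 0 of the 33677 identifiers matched an identifier, accession, symbol or synonym among the 26870 genes of the RefSeq table of assembly Billie_1.0. No gene could therefore be given a symbol, a function or a position. Before the data were examined, gene lists (flagellum, meiosis, energy metabolism, ribosome, stress, cell type markers and others) and a rule for named genes had been fixed. The rule took up to 8 genes with a symbol of their own in each direction, with adjusted p under 0.05, an average log2 CPM of 3 or more and the same direction in at least 24 of the 30 males, and members of the lists. It also took the 5 genes with the highest mean CPM in fresh sperm, which are given only by the range of their levels. Without symbols, none of the lists could be tested, and no gene met the first part of the rule. The few identifiers given were chosen after their values were seen. Hatch rates and the other measurements of the males were not used here, so males with high and low hatch success were not compared.

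Total counts ranged from 929243 to 62118941 per library, and 17 libraries held under 50% of the median total. Genes were kept by edgeR's filterByExpr (32336 genes kept, 1341 left out), counts were scaled by TMM, and cryopreserved and fresh libraries were compared with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) with treatment as the only term. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, and a size limit of 2-fold (log2 fold change of 1) was added for a second count. The 95% intervals of fold changes came from the same fit. In a simulation of this comparison, counts were drawn independently for each gene with the dispersions of the real genes, and 50 genes were changed by each of 4 folds. The changed genes were taken only from those with an average log2 CPM of 1 or more, so the rates do not cover genes below that level. The test recovered 16% of the genes changed 1.5-fold, 58% of those changed 2-fold, 96% of those changed 3-fold and 96% of those changed 4-fold among 32209 genes, with 6 false calls. Unlike in the real libraries, the simulated genes did not vary together, the libraries shared a composition and males were not paired. The rates may therefore not hold for the real comparison.

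Levels per library were log2 CPM (counts per 1000000 counts of the library, TMM, prior count 2). Agreement between the 2 libraries of a male was the median over genes of Pearson's r across the 30 males, set against 1000 random re-pairings of the males. Spread between males was the median over genes of the log2 ratio of the SD in cryopreserved to that in fresh libraries, with 1000 random swaps of the labels within males. Single values per library were compared by 100000 swaps of the labels within males, and single correlations by 100000 permutations. Principal components were computed from the same log2 CPM values, and the first was oriented so that the CPM of the median gene rises along it.

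The numbers pair the samples because they are male numbers and each male's sperm was split. The deviations of a male's 2 libraries from their group means correlated over genes with a median of 0.63, from -0.65 to 0.97, over 0.1 in 22 of the 30 males and under 0 in 7. The fit with the male as a block was an alternative. The other alternatives were DESeq2 size factors, no filter and a stricter filter (10 counts in 30 samples), omission of 10 males with a library under 50% of the median total, omission of the 10 most abundant genes, libraries thinned to 20% of the median total (51 libraries, 9 shallower ones left out), DESeq2 1.42.0, and limma 3.58.1 with voom. Other prior counts (0.5 and 10), rank correlation, the removal of 2 components and the median absolute deviation were tried for the agreement and spread values. Fits with principal components as covariates, and omission of male 35 or of males 35 and 39, and the relations of the first component with depth, were chosen after seeing the data. The expression of single genes along chromosomes, by gene length or by GC content was not analysed here, since the identifiers carry no position. No sequencing batch or date is given in the labels, so no result could be recomputed within batches.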

Results

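Gene expression was profiled by RNA sequencing in the sperm of 30 male blue catfish, each represented by a fresh library and a library made after cryopreservation. Blue catfish males are crossed with channel catfish females in aquaculture, and the series set out to find transcripts in cryopreserved sperm that go with the hatch success of each male. The labels give the treatment of each sample and not the hatch rate, so the comparison made here is cryopreserved against fresh sperm of the same males.

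Nearly all listed genes had a count in some library. An even background over most genes, such as genomic DNA or unspliced RNA, stays open, so a count need not be a sperm transcript. Of 33677 genes, 33671 had at least 1 count in some library and 15887 had a count in every library. The number of genes detected was 31111 ± 3401 in fresh and 30839 ± 4164 in cryopreserved libraries (SD, n = 30 each). Total counts were 11953960 ± 7000240 in fresh and 13090190 ± 11928344 in cryopreserved libraries (SD, n = 30 each). The mean differences within males in total counts and in genes detected did not pass the threshold (within-male permutation test, two-sided, p = 0.729 for total counts and p = 0.582 for genes detected). The cryopreserved library was the deeper of the pair in 13 of the 30 males.

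Depth was shared by the libraries of a male. Log2 total counts of the fresh and the cryopreserved library correlated across males (Pearson r = 0.68, permutation p = 9e-05, Spearman rho = 0.64, permutation p = 0.00023, n = 30), and r was 0.67 without the 2 males farthest from the median. The shallowest library, with 929243 counts, was the cryopreserved sample of male 39, and the deepest, with 62118941 counts, the cryopreserved sample of male 37.

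**Figure D1:**
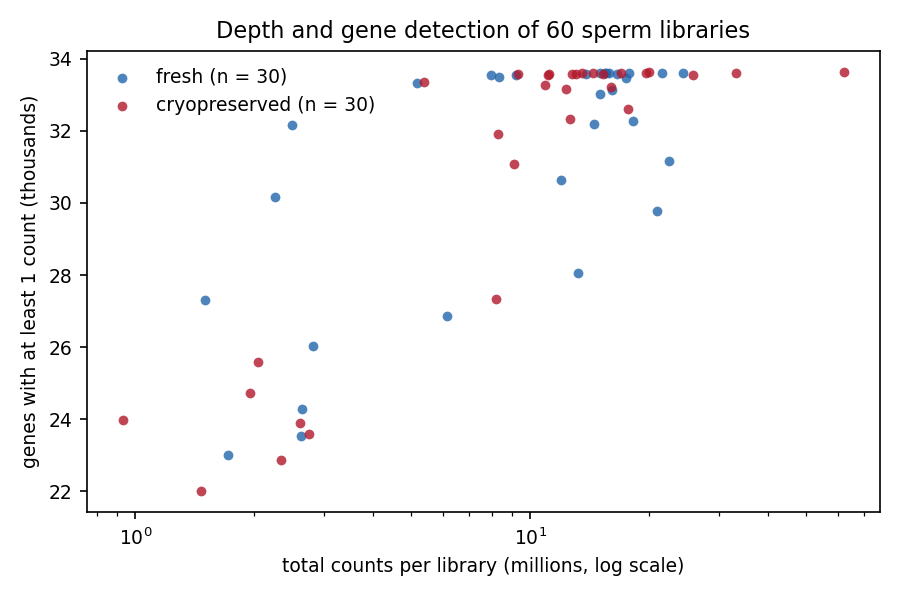
Genes with at least 1 count (vertical axis, in units of 1000 genes) against total counts (horizontal axis, log scale, in units of 1000000 counts) for each of the 60 libraries, 1 point per library, blue for fresh and red for cryopreserved. Fresh libraries detect 23019 to 33615 genes and cryopreserved libraries 21997 to 33638. Only cryopreserved libraries lie below 1503064 or above 24396207 total counts, the lowest and highest fresh totals.

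The most abundant transcripts were largely shared by fresh and cryopreserved sperm. Of the 100 genes with the highest mean level in each group, 94 were in both lists. The 5 genes with the highest mean level had 2069 to 2655 CPM (counts per 1000000 counts of the library) in fresh sperm and the 5 highest in cryopreserved sperm had 2189 to 4343 CPM, and 31 genes had a mean of 1000 CPM or more in each group. The 10 most abundant genes of a library took 2.55% ± 1.57 of the counts in fresh and 3.19% ± 2.79 in cryopreserved libraries (SD, n = 30 each), a difference that did not pass the threshold (within-male permutation test, two-sided, p = 0.149). The difference in percent was 0.637 in all 30 males and 0.182 in the 24 males with both libraries thinned to the same total.

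No gene was called higher or lower in cryopreserved than in fresh sperm in the comparison by treatment alone. Of 32336 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 716 genes, 240 with a higher and 476 with a lower fitted level in cryopreserved sperm. Evenly spread p-values would give 1617 genes, and 50 random splits that, like the real one, part the libraries of every male gave a median of 87.5 and at most 2141, with at least 716 in 3 of them. DESeq2 and limma voom each called 0 genes, with 764 and 835 at an unadjusted p under 0.05. With the male as a block edgeR called 0 genes as well, and with the male as a block and the first 3 principal components as covariates, a fit chosen after seeing the data, it called 4 genes, all 4 higher in cryopreserved sperm and 1 by 2-fold or more. That 1 gene had a low level, with a mean of 0.886 CPM in fresh and 1.65 CPM in cryopreserved sperm.

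In the fit by treatment alone, the interval of the difference was narrow enough to limit its size for most genes. The median absolute log2 fold change was 0.12, and the 95% interval extended by a median of 0.56 to each side. For 29122 genes (90.1% of those tested) the interval excluded a 2-fold difference in both directions, and for 33.3% it excluded a 1.5-fold difference. Only 18 genes had a fitted difference of 2-fold or more, and 0 of these were called. For the other genes, differences of 1.5-fold could not be excluded at this spread, which amounted to a biological coefficient of variation of 69.7%. With the male as a block the interval extended by a median of 0.46, and for 91.8% of genes it excluded a 2-fold difference both ways. The splits that part every male gave far fewer small p-values than evenly spread ones. The 95% is therefore the nominal coverage of the intervals by treatment alone, and the actual one was not measured.

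In the fit by treatment alone the interval was widest for the most abundant transcripts, with a median of 0.89 to each side on the log2 scale. Among the 500 most abundant genes, with a median level of 454 CPM, the median log2 fold change was -0.06 and the interval excluded a 2-fold difference for 51.2%. Among the next 4500 genes by abundance, with a median level of 88.0 CPM, the median was -0.06 and 86.8% excluded it. The 10000 genes after these had a median level of 22.0 CPM and a median log2 fold change of -0.02, and 9497 of them had such an interval. The 17336 genes below that, with a median level of 2.86 CPM, had a median log2 fold change of 0.06, and 89.2% excluded a 2-fold difference. The middle 80% of fold changes lay between -0.24 and 0.11 in the most abundant class and between -0.20 and 0.31 in the least abundant class.

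The genes nearest to a call are given by their identifiers, since the files do not pair these with gene names. AUIFUG00000041011 had 1.45 ± 0.874 CPM in fresh and 3.14 ± 2.77 CPM in cryopreserved sperm (SD, n = 30 each), a log2 fold change of 1.16 with a standard error of 0.28. Its level was above that of the fresh library in 22 of the 30 males, and its edgeR adjusted p was 1.00. AUIFUG00000034698 had 18.4 ± 8.61 CPM in fresh and 12.5 ± 2.67 CPM in cryopreserved sperm, a log2 fold change of -0.55 with a standard error of 0.13. Its level in cryopreserved sperm was above that in fresh sperm in 5 of the 30 males, and its edgeR adjusted p was also 1.00. They were the genes with the smallest unadjusted p in each direction and were chosen after their values were seen. The log2 fold change lay between 0.77 and 1.24 over 13 alternatives of the fit for AUIFUG00000041011, and between -0.57 and -0.33 over 14 for AUIFUG00000034698. The fit on thinned libraries did not cover AUIFUG00000041011. The level of this gene was low, since 3 counts were 3.23 CPM in the shallowest library.

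**Figure D2:**
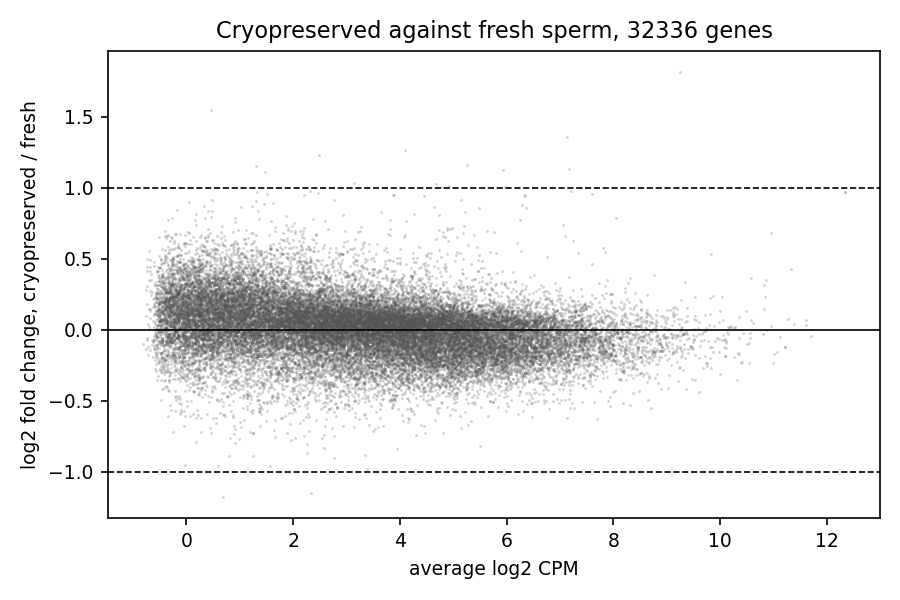
Fitted log2 fold change of cryopreserved over fresh sperm (vertical axis) against average log2 CPM (horizontal axis), 1 point per gene, with dashed lines at a 2-fold difference. The cloud is centred near 0 (median 0.02), 18 of the 32336 genes reach a dashed line, and 0 genes are called.

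Most of the variation between libraries lay on a single component, on which the treatments overlapped. The first principal component of log2 CPM held 62.2% of the variance and the second 7.73%. The largest gap between neighbouring libraries on the first component was 6.32% of the range, which does not by itself exclude groups of libraries. The cryopreserved library lay higher on it than the fresh library in 17 males and lower in 13, with a mean difference of 11.4 ± 165.8 (SD, n = 30 males) over a range of 552.3 (within-male permutation test, two-sided, p = 0.712). The number of genes above 1000 CPM ranged from 1 to 97 in fresh and from 1 to 89 in cryopreserved libraries, and the median gene ranged from 2.20 to 13.8 CPM in fresh and from 1.71 to 13.9 CPM in cryopreserved libraries. Both went with the position. The cryopreserved library of male 23, at 213.6, had 1 gene above 1000 CPM and a median gene of 13.6 CPM. That of male 12, at -332.5, had 89 genes and 1.71 CPM.

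The position on this component was also shared by the libraries of a male (Pearson r = 0.66, permutation p = 0.00018, Spearman rho = 0.62, permutation p = 0.00034, n = 30), and r was 0.59 without the 2 males farthest from the median. The position also went with depth, so that these relations are not separate. In cryopreserved libraries it rose with log2 total counts (Pearson r = 0.73, permutation p = 1e-05, the smallest the permutations can give, Spearman rho = 0.70, permutation p = 3e-05, n = 30), and r was 0.70 without the 2 farthest libraries. In fresh libraries r was 0.37 (permutation p = 0.043, n = 30), rho was 0.28 (permutation p = 0.14) and r without the 2 farthest was 0.29. With log2 total counts removed within each treatment, the positions of a male's libraries correlated with r = 0.46 (permutation p = 0.012, n = 30) and rho = 0.32 (permutation p = 0.084), and r was 0.38 without the 2 farthest, so that the rank relation no longer passed the threshold. Over the 5 relations tested across males, the Benjamini-Hochberg adjusted permutation p of r was 0.000225 for shared depth, 0.0003 for shared position, 5e-05 and 0.043 for position and depth in cryopreserved and fresh libraries, and 0.015 for shared position with depth removed. That of rho was 0.000567, 0.000567, 0.00015, 0.14 and 0.105 in the same order. In 5 males the 2 libraries lay more than 50% of the range apart, and the cryopreserved library was the higher of the pair in 2 of these.

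**Figure D3:**
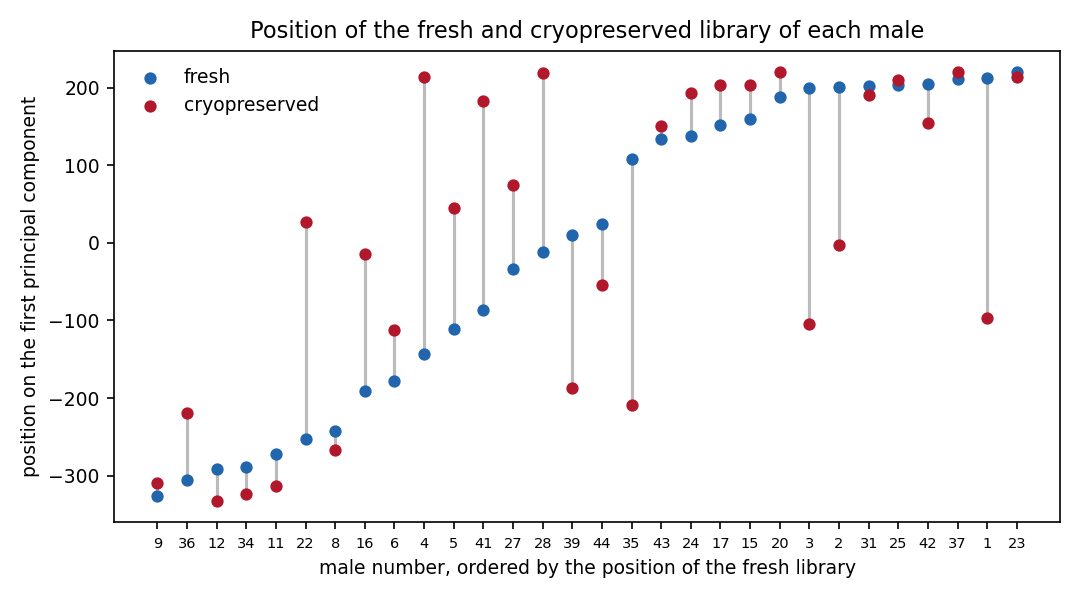
Position of each library on the first principal component of log2 CPM (vertical axis, arbitrary units) for the 30 males (horizontal axis, ordered by the fresh library), blue for fresh and red for cryopreserved, with a grey line joining the libraries of a male. The cryopreserved point is above the fresh point in 17 males and below it in 13, and both colours reach both ends of the component.

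Differences between males in fresh sperm were found again after cryopreservation. The correlation across males between the fresh and the cryopreserved level of a gene had a median of 0.45 over 32336 genes, against a highest value of 0.38 in 1000 random re-pairings of the males (one-sided permutation test, p = 0.001, the smallest that 1000 re-pairings can give). The genes share the first component, whose position also went with depth, and are not independent. With the first 2 components removed the median was 0.10, against at most 0.06 in the re-pairings (one-sided permutation test, p = 0.001). A correlation of 0.7 or more was then held by 330 genes, against a mean of 5.92 and at most 58 in the re-pairings. The margin was smaller in other settings. For the 24 males with both libraries thinned, the median was 0.46, against at most 0.44 in the re-pairings. There 1073 genes reached 0.7, against a mean of 4.70 and at most 1338. By rank correlation the median was 0.40, and the highest re-pairing gave 0.42 (one-sided permutation test, p = 0.002).

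No change in the spread between males was detected after cryopreservation. The SD across males of a gene's log2 CPM had a median of 1.31 in fresh and 1.37 in cryopreserved sperm. The median log2 ratio of the SDs was 0.02, with 17578 of 32336 genes wider in cryopreserved sperm (within-male permutation test, two-sided, p = 0.738). The sign of this ratio was not stable, and it turned negative without male 35 (-0.0044) or with libraries thinned to one total (-0.078).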

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

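The fits with principal components as covariates, the omission of male 35 or of males 35 and 39, the removal of depth from the component's position, and the thinned values of genes detected and of the share of the most abundant genes were chosen after seeing the data, and the other alternatives before. The count of 0 genes from edgeR's quasi-likelihood test was met in 13 of 14 alternatives, with DESeq2 (764 genes at an unadjusted p under 0.05) and limma voom (835) among them, and the smallest adjusted p in these 13 was 0.0909, from DESeq2. With the male as a block there were 0 genes and 973 at an unadjusted p under 0.05. With the male as a block and the first 3 components as covariates, 4 genes were called, 4 higher and 0 lower, and 1 of them by 2-fold or more. That fit gave 3303 genes at an unadjusted p under 0.05, where evenly spread p-values would give 1617, and random splits were not run with it. Of the 4 genes called, AUIFUG00000009527, chosen after its values were seen, was higher in 20 of 30 males. Its log2 fold change was 0.37 with a standard error of 0.06 in that fit (edgeR adjusted p = 0.0106) and 0.39 with a standard error of 0.15 without block and components (edgeR adjusted p = 1.00). The gene called by 2-fold or more, AUIFUG00000043689, had 0.886 ± 1.13 CPM in fresh and 1.65 ± 1.42 CPM in cryopreserved sperm (SD, n = 30 each). Its log2 fold change was 1.54 in that fit, and 0.83 with a standard error of 0.51 without block and components.

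The correlation of the component's position within males was 0.70 without male 35 and 0.46 with depth removed. The median correlation between a male's fresh and cryopreserved levels lay between 0.10 and 0.49 over its 9 alternatives and stayed on its side of the threshold in each of them. The log2 ratio of spreads stayed short of the threshold in all 8 of its alternatives, but its sign turned in 5. It was -0.0029 for genes with a mean of 10 CPM or more, -0.078 with thinned libraries, -0.10 for the median absolute deviation, -0.0044 without male 35 and -0.032 without males 35 and 39, and the cause was not tested. The difference in genes detected was -272 as deposited, -54.7 without male 35 (permutation p = 0.906), so that 1 male carries most of it, and 480 in the 24 males with both libraries thinned to one total (permutation p = 0.378), and the cause was not tested. The difference in the percent of counts in the 10 most abundant genes was 0.637 as deposited and 0.182 in the 24 thinned males (permutation p = 0.465). The tests of gene lists were not run, since no identifier had a symbol. Depth limits 17 libraries of 10 males, which held under 50% of the median total. Without these males 0 genes were called, with 1137 at an unadjusted p under 0.05.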

Other observations

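All tests in this part were chosen after the results they bear on had been seen, and the readings below are hypotheses. No biological explanation tied to hatch success was tested, since hatch rates were not used here.

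Most of the variation between libraries lay on a single axis, the first principal component. Along it, 21411 of 30805 genes with a mean of 1 CPM or more rose (r over 0.5) and 4807 fell, while 3 of the rising genes (0.0140%) and 163 of the falling genes (3.39%) exceeded 1000 CPM in any library. Unequal numbers of counts as the whole cause are argued against by thinning, for the 51 libraries and 24254 genes it kept. Their first component held 75.3% of the variance and had an absolute correlation of 0.99 with the axis. Thinning left out the 9 shallowest libraries and does not even out what may lie behind a low depth. A few dominant genes as the whole cause are argued against by their share. The 10 most abundant genes took at most 12.4% of the counts in any library. Cryopreservation as the whole cause is argued against by the positions, higher in the cryopreserved library in 17 males and lower in 13. The axis was oriented so that the CPM of the median gene rises along it, and the CPM of a library have a fixed sum. More rising than falling genes, and few abundant ones among the rising, were thus largely set in advance. The 0.0140% therefore decides nothing about another cell type at the end where most genes are higher. At the other end, the 3.39% would go with a cell type with abundant transcripts of its own or with abundant transcripts of sperm. No gene names were at hand to tell these. A varying share of an even background over most genes, such as genomic DNA or unspliced RNA, may also account for it and stays open.

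Beyond this axis the libraries of a male resembled each other. With 2 components removed and 500 genes chosen on the other males only, 25 of 30 fresh libraries were closest to the cryopreserved library of their own male, against at most 4 in 100 random re-pairings. Of the cryopreserved libraries, 26 of 30 were closest to the fresh one of their own male, a count for which no re-pairings were run. Depth shared within a male as the whole cause is argued against, for the 24 males with both libraries thinned, by 23 of 24 fresh and 22 of 24 cryopreserved libraries so matched. Thinning left out males 35, 36 and 39, whose fresh libraries had not been matched, so the shares are not comparable with those of all 30 males. It evens out the number of counts only, and not what may lie behind a low depth. Levels specific to each male may therefore persist through cryopreservation. Inherited differences, differences in sample collection and shared handling of a male's aliquots were not separated by any test.

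The libraries of male 35 did not match. In the 4 settings with 2 or 5 components removed their correlation lay between -0.33 and -0.11, and the own partner ranked between 21 and 30 of 30, which was so in 0 other males. With 0 components removed the correlation was -0.24 and -0.16 and the rank between 15 and 25. This was not particular to male 35, since male 22 then had -0.16 and -0.22 and ranks between 13 and 23. Across genes, which are not independent, the fresh library was closest to the fresh library of male 11 in both settings tried (r = 0.49 with 2 components removed, 0.33 with 5), and the cryopreserved library to the fresh library of male 20 (0.34 with 2) or the cryopreserved library of male 11 (0.62 with 5). A library that carries the wrong male number could account for the mismatch, and so could too few counts. In male 36, whose libraries are both shallower, the rank of the own partner ranged from 1 to 19 in the 4 settings. Its own correlation was above 0 in all 4 (0.02 to 0.27). The same held in male 39, also shallower in both libraries (0.01 to 0.25, ranks 1 to 17). Males 9 and 34 had somewhat more counts than male 35, with 2620325 and 2638494 against 2489005 in the fresh library. In the cryopreserved library they had 2610086 and 2751295 against 2044890. In male 9 the own partner ranked 1 both ways in all 4 settings (0.24 to 0.53). In male 34 the ranks lay between 1 and 4 (0.16 to 0.32). Such totals did not prevent a match in male 9, or in male 34 with 2 components removed. Since males 36 and 39 did not match in every setting, depth was still not told apart from a wrong number.

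The count of genes and the count with a 2-fold difference were 0 in the real split, which any split reaches by construction (101 of 101 splits of the 60 libraries, the real one included), so these counts decide nothing about chance. In the 50 drawn splits that part the libraries of every male, as the real one does, the highest count was 0. At an unadjusted p under 0.05 these 50 splits gave a median of 87.5 genes and at most 2141, and 3 of them gave at least the 716 genes of the real split. The other 50 splits kept some males together, and 2 of them called any gene. The highest called 3657 genes, 496 of them with a 2-fold difference, with 16 males parted. Whether this 1 split follows a structure of the samples was not tested.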
